A study of Mus musculus with 72 samples.

How the data were processed

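RNA was measured in nuclei of 36 mouse livers, in bead-bound hepatocyte nuclei and in whole liver nuclei of each animal. Per the labels' protocols, nuclei went directly into Trizol, total RNA was made into stranded libraries without selection of poly-adenylated RNA, and libraries were sequenced as 50-base paired-end reads on a HiSeq 4000. Supernatant nuclei, which the protocols mention, were not analysed here. Reads were aligned to mm10 with STAR 2.4.2a, per the submitters' processing notes, which also name DESeq2 1.24.0 without giving its role. The deposited table holds raw counts of 20105 genes in 72 libraries, counted over the whole gene span with introns, per the file headers. The values are whole numbers, and the counted length equals the gene span except in 946 genes, of which part was left out. Neither headers nor labels state how strand was used, so counts of overlapping and antisense genes cannot be told apart. The table has no mitochondrial genome, ribosomal RNA or long non-coding RNA genes, and 2208 of its genes have no count in any library. The sex of the animals is not in the labels. Columns were matched to animals by the animal number in their names.

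Counts from these files were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Within each fraction the 36 libraries entered a common fit of 9 groups of 4 animals, and the comparisons between fractions a common fit of all 72 libraries in 18 groups. Genes were kept with filterByExpr by group (13274 in hepatocyte nuclei, 13738 in whole liver nuclei and 14054 in the joint fit), and libraries were scaled with TMM (factors 0.900 to 1.12 and 0.905 to 1.14). Genes were tested with the quasi-likelihood F test of edgeR and called at a Benjamini-Hochberg adjusted p under 0.05; every p of a single gene is from this test unless another tool is named. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use TMM-scaled library sizes, and errors beside CPM are SD over animals. Folds are 2 raised to the fitted log2 fold change.

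Each tumour group was compared with the PBS animals of its own cohort, in each fraction, and cachectic C26 animals also with pre-cachexia animals. Differences between tumour effects (C26 and NC26, 8025 and MC38, C26 and 8025) and between fractions were tested as contrasts in the same fits. The overlap of called genes was compared with the overlap of independent calls. Because both C26 groups share their PBS animals, their correlation was set beside simulated unchanged groups against those animals, and recomputed with the PBS animals divided between the comparisons.

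Gene lists (29 of pathways and processes, and 12 of cell types) were written before the data were examined, as were the tests, the samples, the rule for named genes and the alternatives, except where stated. Lists were tested with camera on the edgeR counts (limma; preset correlation between genes 0.01), with Benjamini-Hochberg adjustment over all lists in a comparison. Each was tested again with an estimated correlation, and with fry of limma as a further planned check. Lists with fewer than 5 tested members were not tested, so that 37 lists entered in hepatocyte nuclei and 39 in whole liver nuclei. A list's counts of called genes are given over all genes and again after adjustment over the list alone. Lists share members, and camera at the preset correlation calls more lists than with an estimated correlation.

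Named genes follow a rule. In each tumour comparison in hepatocyte nuclei they are the 5 highest and 5 lowest log2 fold changes among called genes with a mean of at least 5 CPM and no overlap between the values of both groups. Unnamed gene models, pseudogenes, small RNA and Y-linked genes were passed over. The 2 members with the smallest p follow from each of the 8 pathway lists with the highest share of called members (at least 3 called). Nr1d1, Nr1d2, Arntl, Lbp, Itih3, Igfbp1, Saa1 and Igf1 were followed throughout. In whole liver nuclei the ends held 3 genes each. For the comparison of fractions, the markers are the 2 most abundant members of each cell type list. The text describes a part of these genes, and some that the rule names are not reported here.

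Total counts per library had a median of 26.1 M in hepatocyte and 20.1 M in whole liver nuclei, with a lowest value of 8.49 M. The spread between replicate libraries exceeded counting error (chi-square per degree of freedom 22.7 to 372 over 108 pairs). This was computed over genes with at least 20 counts in a pair, and says nothing about depth for genes with fewer counts. No replicate pair had identical counts. Between 0.944% and 8.31% of counts lay in 5 genes with rRNA-like reads (Cmss1, Lars2, Cdk8, Camk1d and Gphn). Both libraries of an animal pair by its number in the labels. Within groups, 34 of 36 hepatocyte libraries correlated best with the whole liver library of their own animal (median correlation of deviations 0.61, from -0.22 to 0.85); C26 PBS 1 and 4 did not. The fit with the animal as a block was therefore run beside the fits of both fractions.

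The steps were tested on simulated data with 200 genes changed by 2-fold or 4-fold. Genes were simulated independently, so correlation between genes in real animals is not covered. For C26 cachexia in hepatocyte nuclei, edgeR recovered 63.6% of 2-fold and 92.0% of 4-fold changes. Between C26 and NC26 it recovered 40.0% and 76.0%. Over the simulated comparisons, 2.48% to 6.38% of edgeR calls were false. For DESeq2 (not run between fractions) it was 7.14% to 13.6%. A list raised 1.5-fold was called by camera in 5 of 6 tests, not in the difference between fractions (adjusted p = 0.065).

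Alternatives were the Wald test of DESeq2, its size factors in edgeR, no filter, the replicate number or the animal as a block, fits of only the cohorts compared, and each replicate left out in turn. After the data were seen, fits without the 5 genes with rRNA-like reads and without the libraries that stood apart were added (hepatocyte nuclei of C26 PBS 1 and 8025 PBS 3, whole liver nuclei of C26 PBS 1 and 8025 PBS 1), and size factors of DESeq2 for the genes called in both cachexia models. In the joint fit of both fractions, leaving out the libraries that stood apart removed both libraries of those animals. Of the 8025 PBS group only animals 2 and 4 then remained. A planned fit without mitochondrial and ribosomal RNA genes would remove no gene and was not run. Other splits of the libraries into groups of the same sizes were fitted for each count of called genes.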

Results

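The study measured RNA in liver nuclei of 36 mice, with 2 libraries from each animal and 72 libraries in all. The mice carried Hep-INTACT transgenes, in which Albumin-Cre switches on a green fluorescent tag on the nuclear membrane of hepatocytes, so that beads can pull hepatocyte nuclei out of a liver. Each animal gave a library of bead-bound hepatocyte nuclei and a library of whole liver nuclei. Animals received PBS or tumour cells of their own strain. C26 cells in BALB/c mice and 8025 cells in C57BL/6N mice induce cachexia, a wasting of body mass. NC26 cells in BALB/c mice and MC38 cells in C57BL/6N mice grow tumours without weight loss. Livers were taken at zeitgeber time 9 h, from C26 and 8025 cachexia animals after a loss of over 10% of body weight, and from a further group of C26 animals before cachexia. Each of the 4 cohorts had its own PBS group, and each of the 9 groups held 4 animals.

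Total counts per library ran from 8.49 M (8025 PBS animal 3) to 56.4 M (C26 pre-cachexia animal 2) in hepatocyte nuclei, with a median of 26.1 M. In whole liver nuclei they ran from 12.2 to 30.3 M, with a median of 20.1 M. Strain accounted for a share of 0.983 of the variance along the first principal component of hepatocyte nuclei (28.5% of all variance), and cachexia for 0.801 along the second (25%). Library numbers ran from 6391 to 6437 in the C26 and 8025 cohorts and from 6500 to 6531 in the NC26 and MC38 cohorts, so that number series and kind of tumour coincide; every tumour group was therefore compared with PBS animals of its own cohort. Library C26 PBS 1 of hepatocyte nuclei stood apart, with 7.0% of its counts in 5 genes with rRNA-like reads. All positions are mm10 gene spans that include introns.

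The comparison of both fractions in the 16 PBS animals asked which cell types the bead purification removed. RNA of several endothelial, macrophage and lymphocyte genes was low in hepatocyte nuclei. It was not low for Tox of the T and NK cell list (107% of its whole liver level), Bach2 of the B cell list (109.9%) or Sox5 of the stellate cell list (119.7%), and Slc40a1 of the macrophage list was lower but kept 75.4% (adjusted p = 0.0053). Stab2 (chromosome 10, 86841210 to 87007942), a scavenger receptor of sinusoidal endothelium, fell from 477 ± 60.4 CPM (counts scaled to library size) in whole liver nuclei to 75.5 ± 23.6 CPM (SD, n = 16), or 15.6% of its whole liver level. Mrc1 (chromosome 2, 14229414 to 14332023), the mannose receptor of macrophages, kept 12.9%, and Bank1 (chromosome 3, 136053364 to 136326066), a B cell scaffold protein, 10.9%. Cps1 (chromosome 1, 67123027 to 67231267), the entry enzyme of the urea cycle in hepatocytes, held 6336 ± 1234 CPM against 5766 ± 1305 CPM, a log2 fold change of 0.14 (SE 0.16, adjusted p = 0.49).

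Of 22 endothelial genes, 21 were lower in hepatocyte nuclei and 1 was not called (22 lower adjusted over the list alone), with a median log2 fold change of -2.56. The call of this list had adjusted p = 2.2e-36, and adjusted p = 7.5e-04 with an estimated correlation. Of 19 Kupffer cell and macrophage genes, 17 were lower and 1 higher (17 and 1 adjusted over the list alone; adjusted p = 5.4e-15). The list of hepatic stellate cells and fibroblasts had 20 lower and 1 higher of 21 (20 and 1 adjusted over the list alone; adjusted p = 5.4e-15). Monocyte genes (11 of 12 lower, 11 adjusted over the list alone), T and NK cell genes (12 of 13, 12 adjusted over the list alone) and extracellular matrix genes (30 of 32 lower and 1 higher, the same counts adjusted over the list alone) were called too. All of these held with an estimated correlation (adjusted p = 0.046 or less). B and plasma cell genes were called lower (10 of 14, and 10 lower and 1 higher adjusted over the list alone), with adjusted p = 0.2 with an estimated correlation. Cholangiocyte genes were not called as a list (9 lower and 2 higher of 15, 10 and 3 adjusted over the list alone, adjusted p = 0.41). Onecut2 (chromosome 18, 64340364 to 64398488), a transcription factor of bile duct cells that hepatocytes share, held 121% of its whole liver level. In all, 3711 of 14054 genes were higher and 3443 lower in hepatocyte nuclei, with 2 and 2557 of them at least 2-fold. With the animal as a block the counts were 5813 and 3967.

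**Figure D1:**
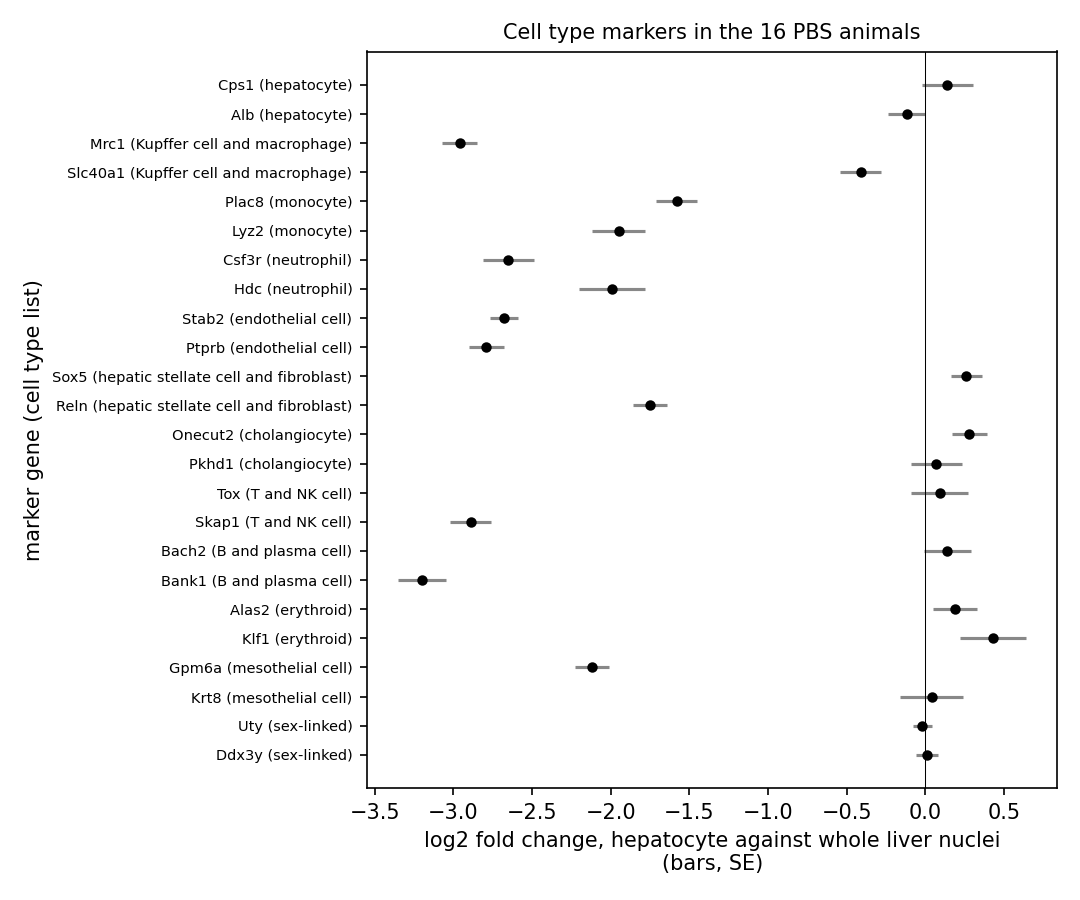
Log2 fold change of marker genes in hepatocyte against whole liver nuclei of 16 PBS animals, for the 2 most abundant members of each cell type list (points, estimates; bars, SE). Stab2 sits at -2.68 and Mrc1 at -2.96, while Cps1 sits at 0.14 and Alb at -0.12.

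The comparison of cachectic C26 animals with PBS animals asked which hepatocyte genes differ once weight has been lost. Acute phase genes, whose products enter plasma during inflammation, rose strongly. Saa1 (chromosome 7, 46740499 to 46742980), which encodes serum amyloid A, stood at 359 ± 112 CPM against 9.26 ± 5.34 CPM (SD, n = 4 each; 38.8-fold; adjusted p = 6.3e-05). Metallothioneins, which bind zinc and copper, rose as well, with Mt2 (chromosome 8, 94172618 to 94173567) at 206 ± 66.0 CPM against 3.61 ± 1.67 CPM (57.2-fold). Among the genes that fell were Slco1a1 (chromosome 6, 141907281 to 141946962), an uptake transporter for bile acids and steroid conjugates, at 33.4 ± 25.6 CPM against 967 ± 184 CPM (29.0-fold lower; log2 fold change -4.86, and -5.57 without cachexia animal 1). Mup21 (chromosome 4, 62147832 to 62150841), a major urinary protein gene, stood at 1.52 ± 0.625 CPM against 109 ± 36.9 CPM (71.6-fold lower).

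Of 28 acute phase genes, 24 rose, 1 fell and 3 were not called (24 and 1 adjusted over the list alone), with a median log2 fold change of 2.89. This was the list with the smallest p (adjusted p = 9.3e-23), and it held with adjusted p = 0.015 with an estimated correlation. Itih3 (chromosome 14, 30908574 to 30923587), an inhibitor chain that binds hyaluronan, reached 3160 ± 244 CPM against 229 ± 62.6 CPM, and Lbp (chromosome 2, 158306493 to 158332852), which carries bacterial lipopolysaccharide, 527 ± 168 CPM against 50.1 ± 11 CPM. Hpx (chromosome 7, 105591611 to 105600116), the haem scavenger hemopexin, rose 6.27-fold. Genes of IL6-JAK-STAT3 signalling were called higher (9 of 20 rose, 9 adjusted over the list alone; adjusted p = 2.0e-05, and adjusted p = 0.091 with an estimated correlation). Complement and coagulation genes were called higher too (14 of 31 rose; 16 higher and 3 lower adjusted over the list alone; adjusted p = 2.0e-04, and adjusted p = 0.36 with an estimated correlation). The coagulation gene F9 (chromosome X, 59999464 to 60030760) stood at 239.7 ± 22.7 CPM against 84.0 ± 16.9 CPM, and Pros1 (chromosome 16, 62854334 to 62929340), an anticoagulant cofactor, rose 3.41-fold. Of 25 glucocorticoid-induced genes, 10 rose (11 higher and 1 lower adjusted over the list alone; adjusted p = 2.7e-04, and adjusted p = 0.36 with an estimated correlation).

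Several metabolic lists were called lower. Of 34 genes of drug and steroid metabolism, 15 fell and 5 rose (15 and 6 adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.36 with an estimated correlation). Ugt2b1 (chromosome 5, 86916639 to 86926503), a glucuronosyltransferase, fell 9.54-fold, and Aox3 (chromosome 1, 58113136 to 58200452), an aldehyde oxidase, 7.76-fold. Fatty acid oxidation and ketogenesis (9 of 34 fell and 2 rose, 11 and 2 adjusted over the list alone, adjusted p = 0.003) and lipogenesis (8 of 23 fell and 2 rose, 9 and 2 adjusted over the list alone, adjusted p = 0.0079) were called lower. These had adjusted p = 0.56 and adjusted p = 0.44 with an estimated correlation. NRF2 targets of oxidative stress were called lower (8 of 23 fell, 10 adjusted over the list alone; adjusted p = 6.2e-04, and adjusted p = 0.36 with an estimated correlation). Amino acid catabolism and the urea cycle were called higher (9 of 42 rose and 2 fell, the same counts adjusted over the list alone; adjusted p = 0.0079, and adjusted p = 0.51 with an estimated correlation). The steroid-converting enzyme gene Hsd3b5 (chromosome 3, 98618636 to 98645534) fell 23.1-fold, and Car3 (chromosome 3, 14863538 to 14872373), a carbonic anhydrase, 37.1-fold. Genes that rose included Sult1e1 (chromosome 5, 87575968 to 87591611), an oestrogen sulfotransferase, at 49.4 ± 55.0 CPM against 0.881 ± 0.970 CPM, and the transcription factor gene Cux2 (chromosome 5, 121860216 to 122047825), at 559 ± 241 CPM against 10.9 ± 5.51 CPM. Without cachexia animal 1 the log2 fold changes were -3.61 for Aox3 (-2.96 with all animals), -5.67 for Hsd3b5 (-4.53) and -5.94 for Car3 (-5.21). That of Sult1e1 was 5.86, and 6.91 without PBS animal 1 or 4.75 without cachexia animal 4.

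Clock genes differed at this time of day. Nr1d1 (chromosome 11, 98767932 to 98775377), the clock repressor REV-ERB alpha, fell to 17.4 ± 15.3 CPM from 60.9 ± 16.6 CPM, and Arntl (chromosome 7, 113207465 to 113314126), the clock activator BMAL1, rose to 108 ± 50.9 CPM from 19.6 ± 6.64 CPM (SD, n = 4; adjusted p = 0.0059 and 5.8e-04, edgeR). Of 18 output genes driven through E-box and D-box elements, 8 fell (8 adjusted over the list alone; adjusted p = 2.8e-04, and adjusted p = 0.19 with an estimated correlation). Nr1d2 (chromosome 14, 18204056 to 18239106), a relative of Nr1d1, had a log2 fold change of -0.76 (SE 0.20, adjusted p = 0.0071), and -0.80 with adjusted p = 0.06 when only the C26 libraries were fitted. Igfbp1 (chromosome 11, 7197787 to 7202546), a binding protein of insulin-like growth factors, rose 29.1-fold (log2 fold change 4.87, and 5.58 without PBS animal 1 or 4.10 without cachexia animal 4). That of Nr1d1 was -1.81, and -2.62 without cachexia animal 3. Igf1 (chromosome 10, 87859056 to 87937047) itself was not called (log2 fold change 0.99, SE 0.53, adjusted p = 0.18).

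Beside these groups, markers of other cells moved. Of 19 Kupffer cell and macrophage genes, 8 rose in the hepatocyte nuclei of cachectic C26 animals (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.003, and adjusted p = 0.44 with an estimated correlation). Monocyte genes were called higher as well (4 of 11, 4 adjusted over the list alone; adjusted p = 0.036, and adjusted p = 0.36 with an estimated correlation). Endothelial genes were not called (6 of 22 rose, 6 adjusted over the list alone, adjusted p = 0.083). Cell cycle genes were called lower (5 of 28 fell, 7 adjusted over the list alone; adjusted p = 6.6e-04, and adjusted p = 0.51 with an estimated correlation). The list of immediate early and heat shock genes was not called (8 of 24 fell and 4 rose, 9 and 4 adjusted over the list alone, adjusted p = 0.11), and its chaperone gene Hspd1 (chromosome 1, 55077834 to 55087932), of mitochondria, fell 2.34-fold. Over all 13274 genes tested with edgeR, 1624 rose and 1329 fell, of which 807 and 466 by at least 2-fold. Each of the called genes named here had all 4 cachexia values beyond all 4 PBS values. Members of near-identical gene families, such as Saa1, Mup21 and Ugt2b1, share reads, so that their counts are uncertain as to the copy.

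**Figure D2:**
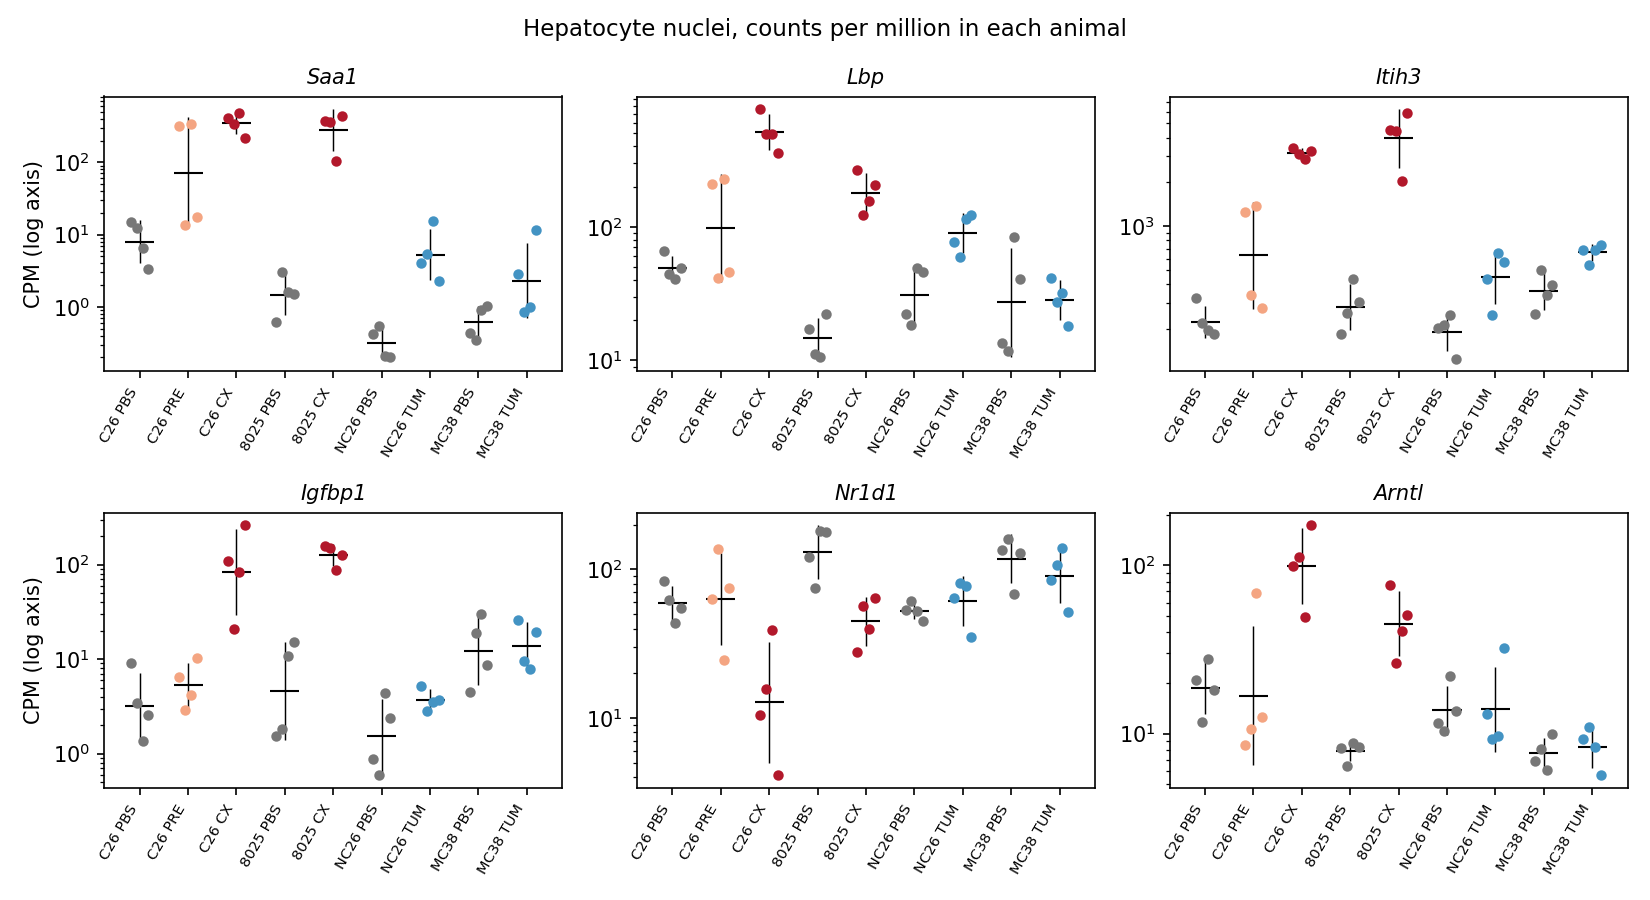
CPM (log axis) of 6 genes in hepatocyte nuclei of each animal (points), with the mean and SD on the log scale in each group of 4 (lines). Itih3 lay between 2850 and 3427 CPM in cachectic C26 animals and between 183 and 320.4 CPM in their PBS animals, and pre-cachexia animals 1 and 3 had Saa1 at 317 and 339 CPM against 13.6 and 17.6 CPM in animals 2 and 4.

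The comparison of cachectic 8025 animals with their PBS animals asked the same of a tumour in another strain. Inflammatory genes rose by up to 283-fold. Lcn2 (chromosome 2, 32384637 to 32387739), which encodes an iron-sequestering protein of the acute phase, stood at 70.0 ± 34.4 CPM against 0.220 ± 0.163 CPM (SD, n = 4; adjusted p = 4.9e-07). Saa1 rose 191-fold, to 319 ± 147 CPM. Hsd3b5 fell to 0.973 ± 0.809 CPM from 379.7 ± 247 CPM (408-fold lower), and Cyp4a12a (chromosome 4, 115299046 to 115332815), a fatty acid hydroxylase gene of the cytochrome P450 family, to 0.739 ± 0.680 CPM from 81.9 ± 39.6 CPM (106-fold lower). Their log2 fold changes were -8.67 (-9.33 without cachexia animal 4) and -6.73 (-7.68 without cachexia animal 3).

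Of 28 acute phase genes, 23 rose, 1 fell and 4 were not called in 8025 animals (24 and 1 adjusted over the list alone), with a median log2 fold change of 2.96 and adjusted p = 1.5e-20. Orm2 (chromosome 4, 63362449 to 63365877), an orosomucoid, rose 127-fold (log2 fold change 6.99, and 8.17 without PBS animal 2), and Apcs (chromosome 1, 172893961 to 172895054), serum amyloid P, 38.4-fold. Genes of IL6-JAK-STAT3 signalling were called higher (10 of 20 rose and 1 fell, the same counts adjusted over the list alone; adjusted p = 1.5e-05). Osmr (chromosome 15, 6813577 to 6874313), the oncostatin M receptor, stood at 111 ± 13.3 CPM against 3.48 ± 0.331 CPM, and Stat3 (chromosome 11, 100886810 to 100939511), the transcription factor of this pathway, rose 2.94-fold. NF-kB targets were called higher, with 12 of 19 up and none down (12 adjusted over the list alone; adjusted p = 3.7e-06). Among them Cxcl1 (chromosome 5, 90891245 to 90893115), a neutrophil attractant, rose 10.5-fold and Icam1 (chromosome 9, 21015960 to 21028796), an adhesion molecule, 4.51-fold. Both of the latter lists held with adjusted p = 0.043 with an estimated correlation, and the acute phase list with adjusted p = 0.013 with an estimated correlation.

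Lipogenesis was the metabolic list with the smallest p in 8025 animals, with 14 of 23 genes lower and 1 higher (16 and 1 adjusted over the list alone; adjusted p = 2.8e-08, and adjusted p = 0.043 with an estimated correlation). Its median log2 fold change was -1.30. Me1 (chromosome 9, 86581363 to 86695914), the malic enzyme that supplies NADPH, fell to 59.3 ± 19.6 CPM from 654 ± 180.4 CPM, and Fads2 (chromosome 19, 10064164 to 10101503), a fatty acid desaturase, fell 6.80-fold. Drug and steroid metabolism (14 of 34 fell and 3 rose, the same counts adjusted over the list alone) was called lower with adjusted p = 0.002, and adjusted p = 0.31 with an estimated correlation. Gluconeogenesis and glycogen (8 of 24 fell and 3 rose, 9 and 3 adjusted over the list alone) was called lower with adjusted p = 0.0051, and adjusted p = 0.25 with an estimated correlation. Of 25 glucocorticoid-induced genes, 9 rose (9 adjusted over the list alone; adjusted p = 0.0028, and adjusted p = 0.37 with an estimated correlation). Igfbp1 rose 18.5-fold, to 130.1 ± 31.9 CPM from 7.35 ± 6.80 CPM (log2 fold change 4.21, and 4.98 without PBS animal 4).

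Clock genes moved in the same direction as in C26 animals. Nr1d1 fell to 47.0 ± 16.4 CPM from 139 ± 50.6 CPM and Arntl rose to 48.6 ± 21.4 CPM from 7.96 ± 1.05 CPM (adjusted p = 0.011 and 3.0e-04). Of 18 E-box and D-box output genes, 11 fell (12 lower and 1 higher adjusted over the list alone; adjusted p = 6.5e-06, and adjusted p = 0.043 with an estimated correlation). Wee1 (chromosome 7, 110122059 to 110143299), a mitotic kinase under clock control, fell 4.20-fold, and Tef (chromosome 15, 81802673 to 81826863), a D-box factor, 2.11-fold. Nr1d2 had a log2 fold change of -0.61 (SE 0.20, adjusted p = 0.023), which missed the threshold without PBS animal 4 (adjusted p = 0.064) or cachexia animals 1, 3 or 4 (0.061, 0.05 and 0.051), and with the replicate number as a block (0.079).

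Markers of other cells rose in 8025 hepatocyte nuclei as well. Of 11 monocyte genes 9 rose (10 adjusted over the list alone), with a median log2 fold change of 2.46 (adjusted p = 2.8e-08, and adjusted p = 0.013 with an estimated correlation). Of 19 Kupffer cell and macrophage genes 14 rose (16 higher and 1 lower adjusted over the list alone; adjusted p = 1.9e-08, and adjusted p = 0.074 with an estimated correlation). Cholangiocyte genes were called higher (10 of 14, 10 adjusted over the list alone; adjusted p = 6.2e-05, and adjusted p = 0.25 with an estimated correlation), and so were extracellular matrix genes (11 of 30 rose and 2 fell, 12 and 2 adjusted over the list alone; adjusted p = 0.0037, and adjusted p = 0.39 with an estimated correlation). In all, 2150 of 13274 genes rose and 1739 fell, of which 1487 and 474 by at least 2-fold. Again the called genes named here had all 4 cachexia values beyond all 4 PBS values.

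Whether the cachexia models share genes was tested on their overlap. Of the genes called, 945 were higher in C26 and in 8025 cachexia where independent calls would give 263, and 724 were lower in both where 174 would be (expected counts from the calls in each model). Of 1680 genes called in both, 1669 had the same sign (99.3%), among them Saa1, Itih3, Lbp, Igfbp1, Arntl, Nr1d1 and Car3. The correlation of log2 fold changes across genes was 0.66, and genes are not independent replicates.

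**Figure D3:**
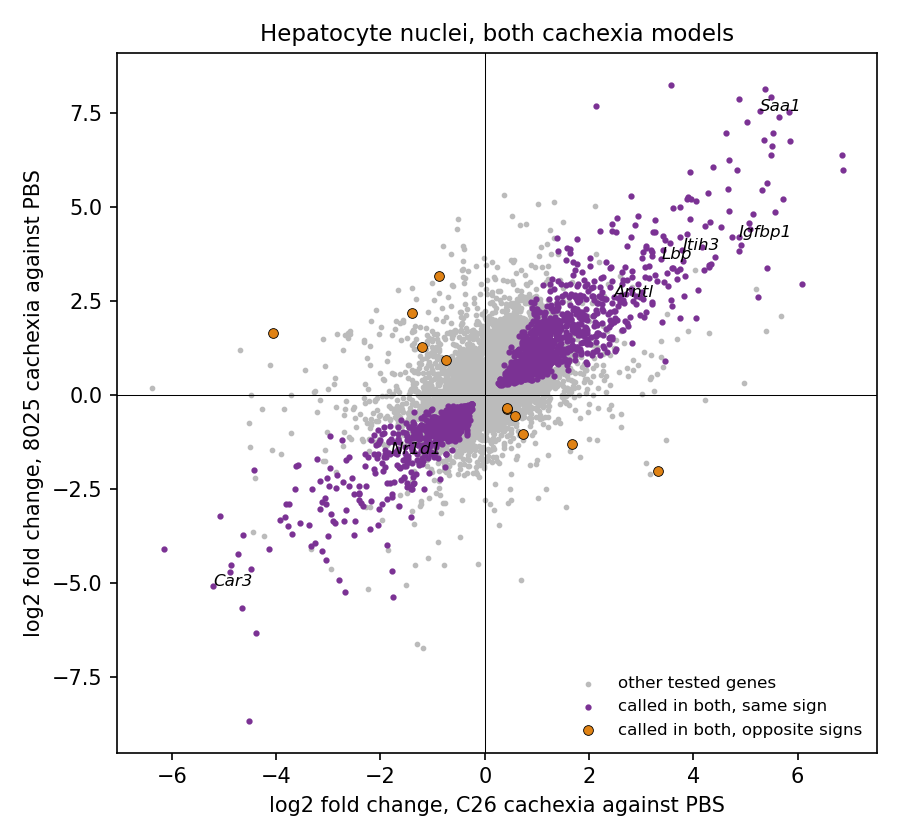
Log2 fold change of each tested gene in hepatocyte nuclei of cachectic C26 animals (x axis) and cachectic 8025 animals (y axis), each against its PBS group. Of 1680 genes called in both, 1669 lie in the quadrants of equal sign and 11 in the others.

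The test of the difference between the models called 52 genes with a higher and 75 with a lower change in C26 than in 8025 (127 of 13274). Adgrl3 (chromosome 5, 81021593 to 81795730), an adhesion receptor, differed by a log2 change of -3.43 (SE 0.37, adjusted p = 1.3e-06). The fall of Cyp4a12a was deeper in 8025, by a difference of 5.55 (SE 0.81, adjusted p = 4.2e-04; 4.72 without C26 cachexia 1 and 6.48 without 8025 cachexia 3). Lipogenesis genes had a lower change in 8025 (2 of 23 called, 4 adjusted over the list alone; adjusted p = 3.4e-05, and adjusted p = 0.25 with an estimated correlation). Monocyte genes had a higher change in 8025 (2 of 11 called; 4 in that direction and 1 in the other adjusted over the list alone; adjusted p = 2.2e-05, and adjusted p = 0.08 with an estimated correlation). Strain and tumour cells differ together between these models. The count of 127 genes was 81 without C26 PBS 2, 51 without C26 cachexia 4, 59 and 60 without 8025 PBS 1 and 2, and 220, 81 and 57 without 8025 cachexia 1, 2 and 3; DESeq2 called 355, and a fit of these cohorts alone 54.

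The comparison of C26 animals before cachexia with PBS animals asked what precedes weight loss. Acute phase and interferon genes were higher, unevenly between animals. Saa1 rose to 172 ± 180.3 CPM from 9.26 ± 5.34 CPM (SD, n = 4; adjusted p = 0.0027), with 317 and 339 CPM in animals 1 and 3 and 13.6 and 17.6 CPM in animals 2 and 4. Hpx rose 4.98-fold, to 583 ± 276 CPM (adjusted p = 3.0e-05), and Nlrc5 (chromosome 8, 94472763 to 94527272), an activator of MHC class I genes, rose 2.72-fold, to 224 ± 77.2 CPM (adjusted p = 1.7e-04). Mup21 had already fallen 10.7-fold, and Pdgfrl (chromosome 8, 40926233 to 40990770), a receptor-like protein gene, fell 11.2-fold.

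Of 30 interferon response genes, 15 rose in pre-cachexia (25 adjusted over the list alone), with a median log2 fold change of 1.21 and adjusted p = 9.2e-21 (adjusted p = 0.05 with an estimated correlation). Psmb8 (chromosome 17, 34198195 to 34201454), a subunit of the immunoproteasome, rose 3.83-fold. Of 28 acute phase genes, 17 rose and 1 fell (21 and 1 adjusted over the list alone; adjusted p = 2.1e-12, and adjusted p = 0.096 with an estimated correlation). Orm2 rose 21.3-fold and Orm1 (chromosome 4, 63344566 to 63348162) 9.39-fold, with log2 fold changes of 4.42 (3.55 without pre-cachexia animal 1) and 3.23 (2.54 without pre-cachexia animal 3). Itih3 rose 3.51-fold (adjusted p = 0.0049), while Lbp was not called (log2 fold change 1.38, SE 0.51, adjusted p = 0.091). Lbp had adjusted p = 0.05 without pre-cachexia animal 2 and 0.049 in DESeq2. IL6-JAK-STAT3 genes were called higher (5 of 20, 9 adjusted over the list alone; adjusted p = 5.4e-04, and adjusted p = 0.12 with an estimated correlation). Socs3 (chromosome 11, 117966087 to 117969366), the feedback inhibitor of this pathway, rose 7.23-fold. NF-kB targets were called higher (4 of 19 rose; 7 higher and 1 lower adjusted over the list alone; adjusted p = 7.8e-05, and adjusted p = 0.096 with an estimated correlation), with Cxcl1 up 8.93-fold. Complement and coagulation genes were called higher (9 of 31, 16 adjusted over the list alone; adjusted p = 5.8e-08, and adjusted p = 0.096 with an estimated correlation).

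Clock regulators were not called before cachexia. Nr1d1 had a log2 fold change of 0.30 (SE 0.46, adjusted p = 0.74), Nr1d2 -0.01 (SE 0.20, adjusted p = 0.98) and Arntl 0.35 (SE 0.48, adjusted p = 0.71). These signs turned without pre-cachexia animal 2 (Nr1d1 -0.17), without PBS animal 4 or pre-cachexia animal 3 (Nr1d2 0.09 and 0.18), and without pre-cachexia animal 3 (Arntl -0.88). Igfbp1 was not called (0.54, SE 0.71, adjusted p = 0.7), nor was Igf1 (0.97, SE 0.53, adjusted p = 0.27). E-box and D-box output genes were called lower (2 of 18 fell, 2 adjusted over the list alone; adjusted p = 0.0082, and adjusted p = 0.28 with an estimated correlation). Cell cycle genes were called higher (6 of 28 rose; 10 higher and 1 lower adjusted over the list alone; adjusted p = 0.0084, and adjusted p = 0.78 with an estimated correlation). Hsp90aa1 (chromosome 12, 110691036 to 110696395), an abundant chaperone, fell 4.41-fold, to 16.7 ± 8.13 CPM from 73.2 ± 45.5 CPM, while its list of immediate early and heat shock genes was not called (6 of 24 fell and 4 rose, 7 and 5 adjusted over the list alone, adjusted p = 0.5). Kupffer cell and macrophage genes rose beside these groups (8 of 19, 11 adjusted over the list alone; adjusted p = 5.8e-08, and adjusted p = 0.11 with an estimated correlation).

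The called genes named here had no overlap between the 4 values of each group, except Saa1 and Itih3. Before cachexia 635 of 13274 genes rose and 390 fell (1025 called). The count was 1626, 532, 491 and 633 without PBS animals 1, 2, 3 and 4, and 333 and 665 without pre-cachexia animals 1 and 2. It was 404 with only the C26 libraries fitted, and 1723 without the libraries that stood apart, an alternative chosen after the data were seen.

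Cachectic C26 animals were then compared with those before cachexia. Interferon genes were lower in cachexia (17 of 30, 25 adjusted over the list alone), with a median log2 fold change of -1.42 (adjusted p = 4.4e-20, and adjusted p = 0.044 with an estimated correlation). Acute phase genes were higher (13 of 28, 13 adjusted over the list alone; adjusted p = 2.4e-11, and adjusted p = 0.12 with an estimated correlation). Cell cycle genes were lower (12 of 28, 19 adjusted over the list alone; adjusted p = 6.0e-13, and adjusted p = 0.17 with an estimated correlation). Glucocorticoid-induced genes (10 of 25, 13 adjusted over the list alone) were higher with adjusted p = 8.7e-09, and adjusted p = 0.15 with an estimated correlation. Amino acid catabolism and the urea cycle (15 of 42 higher and 1 lower, 16 and 1 adjusted over the list alone) was higher with adjusted p = 3.1e-07, and adjusted p = 0.19 with an estimated correlation. Sult1e1 was 147-fold higher, Cyp17a1 (chromosome 19, 46667165 to 46673000), a steroid hydroxylase, 32.9-fold higher, and Atp6v0a4 (chromosome 6, 38048483 to 38124586), a proton pump subunit, 46.3-fold higher. Hsd3b5 was 30.6-fold lower, Car3 16.5-fold lower and Mup9 (chromosome 4, 60418046 to 60421952) 15.1-fold lower. The log2 fold change of Sult1e1 was 7.2, and 7.81 without pre-cachexia animal 4 or 6.09 without cachexia animal 4, and that of Cyp17a1 5.04, and 5.70 without pre-cachexia animal 1. Those of Atp6v0a4 (5.53), Hsd3b5 (-4.94) and Car3 (-4.05) were 4.73 without cachexia animal 4, and -6.08 and -4.78 without cachexia animal 1. In all, 639 genes were higher and 567 lower (1206 called), 604 without pre-cachexia animal 2, 568 without cachexia animal 4, and 776 with only the C26 libraries fitted.

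Both C26 groups were set against the same PBS animals, which makes their changes alike even where nothing differs. Of the genes called before cachexia, 409 of 635 higher ones were also higher in cachexia (77.7 expected of independent calls) and 276 of 390 lower ones were also lower (39.0 expected). The correlation across genes was 0.59, against 0.52 on average (highest 0.54) in 20 simulations of unchanged groups with shared controls. The covariance was 0.28, against 0.06 in those simulations. With the PBS animals divided between the comparisons, in 6 orders, the correlation was 0.32 to 0.44 and the covariance 0.19 to 0.24. In those orders 90 to 136 genes were higher in both (at most 31.0 expected) and 33 to 88 lower in both (at most 20.6 expected).

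The tumours without weight loss gave few calls. In NC26 animals 42 of 13274 genes rose and 1 fell. Fgl1 (chromosome 8, 41191434 to 41215156), a secreted protein of hepatocytes, rose to 186 ± 115 CPM from 4.28 ± 2.60 CPM (SD, n = 4; 43.3-fold; adjusted p = 3.7e-04). Rad51b (chromosome 12, 79297282 to 79814690), a DNA repair gene, rose 11.2-fold, to 721 ± 291 CPM, and Slc37a1 (chromosome 17, 31295483 to 31350698), a sugar phosphate exchanger, 7.29-fold. Saa1 stood at 6.84 ± 6.00 CPM against 0.346 ± 0.170 CPM but was not called (adjusted p = 0.067). It was called without tumour animal 2 (0.048), with only the NC26 libraries fitted (0.035) and in DESeq2 (2.3e-04), and its highest adjusted p over the alternatives was 0.19. Its log2 fold change was 4.30, and 3.48 to 4.61 over the alternatives. Itih3 was not called (log2 fold change 1.29, adjusted p = 0.16; 0.049 in DESeq2), nor were Lbp (1.46, adjusted p = 0.24), Igfbp1 (0.92, adjusted p = 0.64), Nr1d1 (0.29, adjusted p = 0.84) and Nr1d2 (0.21, adjusted p = 0.7). Arntl was not called (0.16, adjusted p = 0.93; -0.41 without tumour animal 4), nor was Igf1 (0.16, adjusted p = 0.93; -0.02, -0.06 and -0.35 without PBS animals 3 and 4 and tumour animal 2). Of the 42 genes that rose, 40 also rose in C26 cachexia (5.14 expected), 37 in 8025 cachexia (6.80 expected) and 37 before cachexia (2.01 expected). For C26 cachexia, Fisher's exact test on genes gave p = 1.4e-34, which is only descriptive, since genes are not independent replicates.

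As a list, acute phase genes were called higher in NC26 animals (2 of 28 rose; 15 higher and 1 lower adjusted over the list alone; median log2 fold change 1.17; adjusted p = 4.1e-15, and adjusted p = 0.093 with an estimated correlation). Cell cycle genes (1 of 28 rose, 12 adjusted over the list alone; adjusted p = 1.1e-08) and interferon genes (2 of 30 rose, 6 adjusted over the list alone; adjusted p = 5.1e-09) were called higher. Each had adjusted p = 0.3 with an estimated correlation. In NC26 hepatocyte nuclei the fry check called 2 lists in all, where camera called 11. The count of 43 genes was 10, 4, 24 and 10 without PBS animals 1, 2, 3 and 4, and 13, 94 and 27 without tumour animals 1, 2 and 3; DESeq2 called 143.

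In MC38 animals edgeR called 0 of 13274 genes. At an unadjusted p under 0.05 there were 572, where chance would give 664, and DESeq2 called 6. The edgeR count was 1 without PBS animal 3 and 5 without tumour animal 1. Animal numbers form series that cross both MC38 groups, and no fit took these series up. Saa1 stood at 4.06 ± 5.06 CPM against 0.673 ± 0.332 CPM (SD, n = 4, adjusted p = 0.85). It was 11.5 CPM in tumour animal 4 and 0.848 to 2.87 CPM in the others. Itih3 stood at 666 ± 84.1 CPM against 371 ± 104 CPM (adjusted p = 1). Nr1d1 had a log2 fold change of -0.37, Nr1d2 -0.05 (0.00 and 0.08 without tumour animals 1 and 4), Arntl 0.13 and Igf1 0.90 (adjusted p = 1 each). Lbp had -0.35 (0.46 without PBS animal 3) and Igfbp1 0.01 (-0.30, -0.17, -0.31 and -0.11 without PBS animals 1 and 4 and tumour animals 1 and 4), also with adjusted p = 1. As a list, acute phase genes were called higher (0 of 28 by themselves, 6 adjusted over the list alone; median log2 fold change 0.84; adjusted p = 1.3e-12, and adjusted p = 0.096 with an estimated correlation). Kupffer cell and macrophage genes were called higher too (0 of 19 by themselves, 3 adjusted over the list alone; adjusted p = 1.0e-12, and adjusted p = 0.096 with an estimated correlation). The fry check called 0 lists in MC38 hepatocyte nuclei, where camera called 10. In simulated counts with the MC38 group sizes, 60% of 2-fold and 88.9% of 4-fold changes were called.

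**Figure D4:**
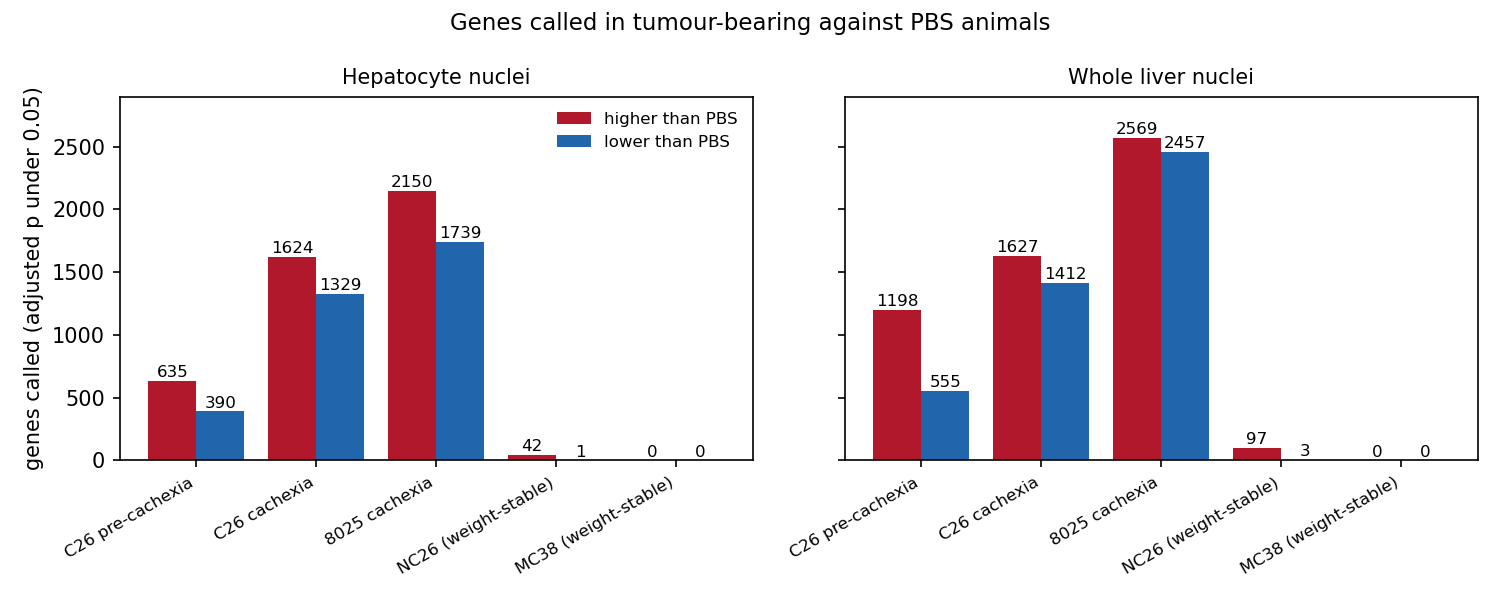
Number of genes called higher (red) and lower (blue) than in PBS animals in hepatocyte nuclei (left) and whole liver nuclei (right), edgeR at an adjusted p under 0.05, 4 animals a group. Cachexia gave 1624 and 1329 genes in C26 and 2150 and 1739 in 8025 hepatocyte nuclei, and MC38 tumours 0 in each fraction.

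The change in cachexia was tested against the change under the weight-stable tumour of the same strain. Between C26 and NC26, 124 genes had a higher and 127 a lower change in cachexia (251 of 13274). Mup21 fell further in C26 by a log2 difference of -5.05 (SE 0.76, adjusted p = 3.4e-04), and Slco1a1 by -4.48 (SE 0.69, adjusted p = 4.4e-04; -5.20 without C26 cachexia 1). Lppr1 (chromosome 4, 49059462 to 49340261), a membrane protein gene, rose further by 4.33 (SE 0.57, adjusted p = 7.5e-05), and Itih3 by 2.50 (SE 0.54, adjusted p = 0.011). Nr1d1 (-2.10, SE 0.65, adjusted p = 0.089), Arntl (2.31, SE 0.69, adjusted p = 0.073), Lbp (1.93, SE 0.71, adjusted p = 0.16) and Saa1 (0.98, SE 1.41, adjusted p = 0.82) were not called. Acute phase genes had a higher change in C26 cachexia (5 of 28, 16 adjusted over the list alone; adjusted p = 1.3e-11) and cell cycle genes a lower (4 of 28, 20 adjusted over the list alone; adjusted p = 4.2e-15). Both had adjusted p = 0.18 with an estimated correlation. The count of 251 genes was 479 without C26 PBS 1, 153 without C26 cachexia 3, 137 without NC26 PBS 1 and 163 without NC26 tumour 1. It was 506 in DESeq2 and 489 without the libraries that stood apart.

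Between 8025 and MC38, 556 genes had a higher and 401 a lower change in cachexia (957 of 13274, and 623 without 8025 PBS 2). Mt2 rose further by 7.19 (SE 1.27, adjusted p = 7.7e-04; 5.84 without MC38 PBS 3) and Igdcc4 (chromosome 9, 65101486 to 65137947), an immunoglobulin superfamily gene, by 7.83 (SE 1.5, adjusted p = 0.0016; 8.49 without 8025 PBS 2). Hsd3b5 fell further by a difference of -8.64 (SE 1.09, adjusted p = 1.2e-05) and Cyp4a12a by -5.63 (SE 0.81, adjusted p = 6.2e-05). These were -9.31 without 8025 cachexia 4 and -7.95 without MC38 tumour 2 for Hsd3b5, and -6.59 without 8025 cachexia 3 for Cyp4a12a. Lbp (3.95, SE 0.74, adjusted p = 0.0012), Itih3 (3.0, SE 0.55, adjusted p = 9.1e-04), Igfbp1 (4.20, SE 0.99, adjusted p = 0.0088), Saa1 (4.91, SE 1.37, adjusted p = 0.025) and Arntl (2.48, SE 0.71, adjusted p = 0.028) had a higher change in cachexia. Nr1d1 was not called (-1.20, SE 0.65, adjusted p = 0.27). Acute phase genes had a higher change (14 of 28; 20 higher and 2 lower adjusted over the list alone; adjusted p = 1.4e-16, and adjusted p = 0.07 with an estimated correlation). Lipogenesis had a lower change (6 of 23 lower and 1 higher, 10 and 1 adjusted over the list alone; adjusted p = 5.0e-06, and adjusted p = 0.12 with an estimated correlation).

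**Figure D5:**
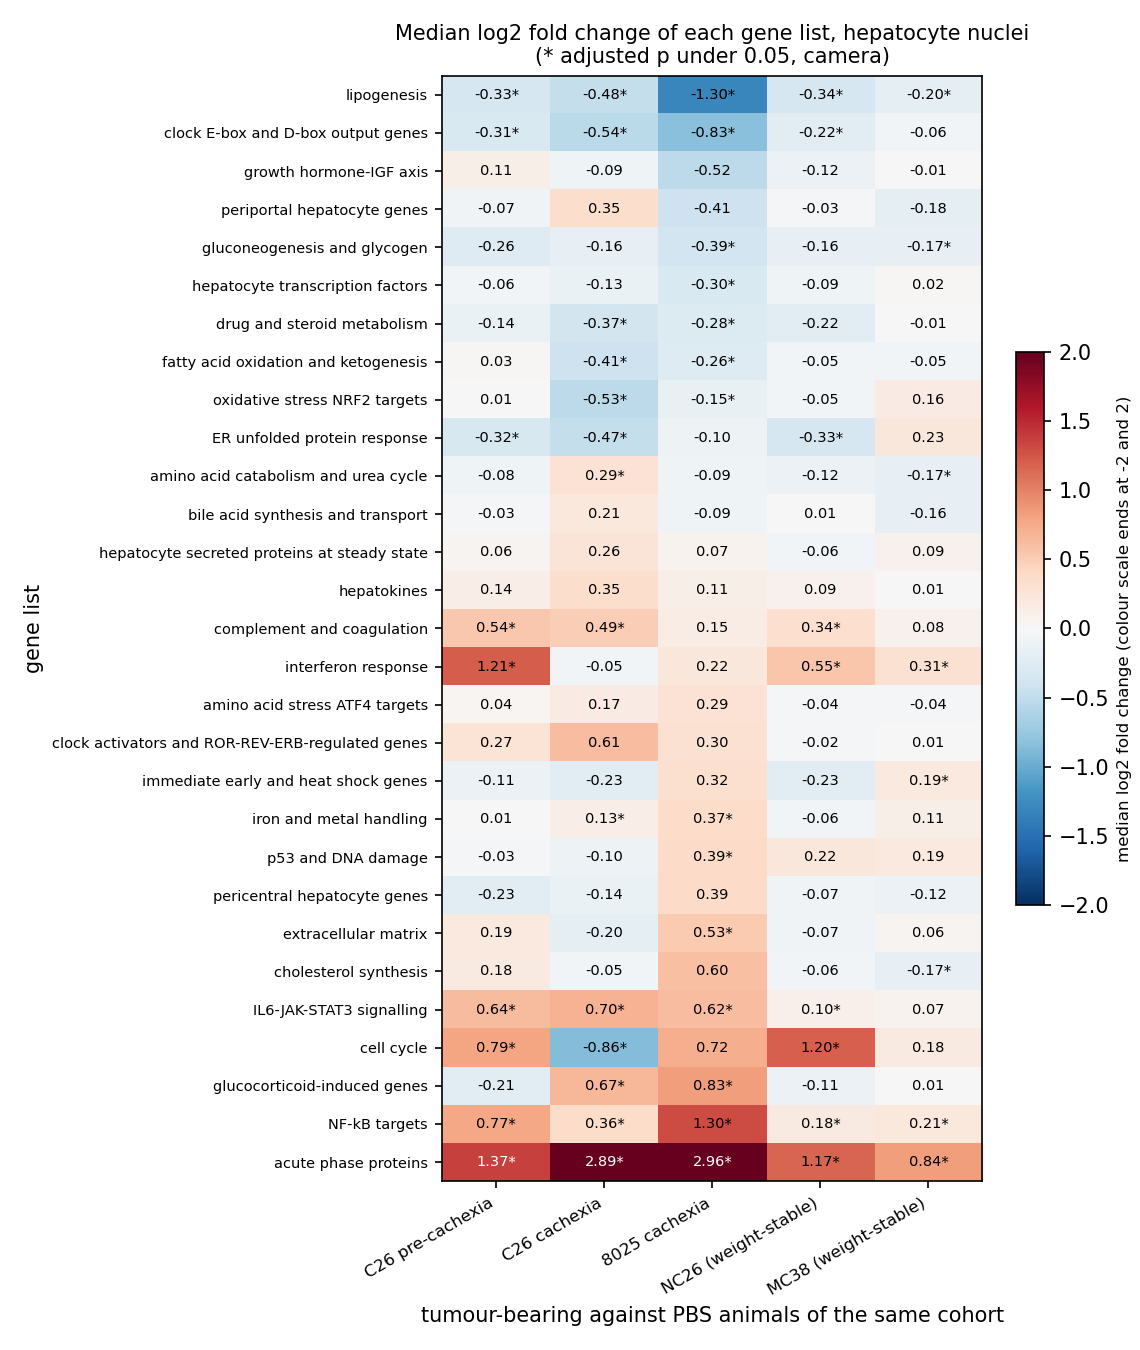
Median log2 fold change of 29 gene lists in hepatocyte nuclei (colour scale from -2 to 2) in each of 5 comparisons with PBS animals, with a star where the camera test called the list. Acute phase genes have medians of 1.37, 2.89, 2.96, 1.17 and 0.84 from left to right, and lipogenesis -0.33, -0.48, -1.30, -0.34 and -0.20.

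Whole liver nuclei showed immune cell genes beside the hepatocyte changes. In cachectic 8025 livers, Itgam (chromosome 7, 128062640 to 128118491), an integrin of myeloid cells, rose to 24.6 ± 4.28 CPM from 1.69 ± 0.124 CPM (SD, n = 4; 14.5-fold; adjusted p = 8.5e-13). Csf3r (chromosome 4, 126024659 to 126044975), the receptor that drives neutrophil production, rose 8.28-fold, to 42.2 ± 7.97 CPM, and Il1r2 (chromosome 1, 40084768 to 40125226), a decoy receptor of interleukin 1, 94.1-fold. In cachectic C26 livers these genes rose less, Itgam 2.75-fold, Csf3r 2.01-fold and Il1r2 15.1-fold (log2 fold change 3.92, and 5.0 without PBS animal 1), and this difference was not tested in whole liver nuclei. Ebf1 (chromosome 11, 44618100 to 45008096), a B cell transcription factor, fell 1.90-fold in 8025 livers.

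Of 12 neutrophil genes, 11 rose in 8025 (12 adjusted over the list alone; adjusted p = 9.4e-13, and adjusted p = 5.5e-04 with an estimated correlation) and 7 in C26 cachexia (9 adjusted over the list alone; adjusted p = 5.3e-05, and adjusted p = 0.036 with an estimated correlation). Of 12 monocyte genes, 11 rose in 8025 (11 adjusted over the list alone; adjusted p = 4.7e-14, and adjusted p = 0.01 with an estimated correlation) and 4 in C26 (4 adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.49 with an estimated correlation). Of 19 Kupffer cell and macrophage genes, 16 rose in 8025 (17 adjusted over the list alone; adjusted p = 5.7e-12, and adjusted p = 0.033 with an estimated correlation) and 6 in C26 (10 adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.53 with an estimated correlation). B and plasma cell genes fell in 8025 (6 of 14, 9 adjusted over the list alone; adjusted p = 0.028, and adjusted p = 0.38 with an estimated correlation). Before cachexia, Cd5l (chromosome 3, 87357881 to 87371074), a secreted protein of macrophages, rose 4.28-fold, and Cd74 (chromosome 18, 60803849 to 60812652), the MHC class II chaperone, 2.18-fold. T and NK cell genes were then called higher (3 of 12, 3 adjusted over the list alone; adjusted p = 0.0032, and adjusted p = 0.12 with an estimated correlation).

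Hepatocyte genes moved in whole liver nuclei as well. Acute phase genes rose in C26 cachexia (25 of 29 rose and 1 fell, the same counts adjusted over the list alone; adjusted p = 1.1e-32, and adjusted p = 0.0014 with an estimated correlation). In 8025 they rose too (25 and 1; 26 and 2 adjusted over the list alone; adjusted p = 4.8e-16, and adjusted p = 0.019 with an estimated correlation). In all, 1627 genes rose and 1412 fell in C26 cachexia, 1198 and 555 before cachexia, 2569 and 2457 in 8025, and 97 and 3 in NC26, of 13738 genes. The 1753 calls before cachexia were 932 without PBS animal 1, 973 without pre-cachexia animal 1, and 1111 without the libraries that stood apart; the 5026 calls in 8025 were 2981 with only its own libraries fitted. The 100 calls in NC26 were 24, 42, 41 and 60 without PBS animals 1 to 4 and 49, 52 and 64 without tumour animals 1, 3 and 4; DESeq2 called 199. In MC38, edgeR called 0 (790 at an unadjusted p under 0.05; 14 in DESeq2), and 10 without tumour animal 1.

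The change in cachexia was compared between hepatocyte and whole liver nuclei of the same animals. Of the genes called in hepatocyte nuclei and tested in both fractions, 2127 of 2938 were also called in whole liver nuclei of C26 animals (72.4%), and 3112 of 3871 in 8025 animals (80.4%). The correlation across genes was 0.90 and 0.91. Since both fractions come from the same animals, part of this likeness can arise without a change, and no value for unchanged groups was computed. The edgeR test of the difference, which leaves out the pairing of both libraries of an animal, called 0 of 14054 genes in C26. At an unadjusted p under 0.05 there were 295, where chance would give 703. DESeq2 called 1, and the fit with the animal as a block, which takes up the pairing, 62. In 8025 the edgeR test without the pairing called 6 genes, all with a higher change in hepatocyte nuclei. There, 522 genes had an unadjusted p under 0.05, again where chance would give 703. DESeq2 called 8 with a higher and 6 with a lower change, and the fit with the animal as a block 131 and 59 (190 in all). Col8a1 (chromosome 16, 57624256 to 57754737), a short-chain collagen, rose by 3.48 in hepatocyte nuclei and 1.23 in whole liver nuclei on the log2 scale, a difference of 2.26 (SE 0.38, adjusted p = 0.0018). Its call held with the animal as a block, and was lost with only the 8025 libraries fitted (adjusted p = 0.058). It was also lost without the libraries that stood apart (0.35), where only PBS animals 2 and 4 of 8025 were left in their group. Osmr rose by 5.0 and 2.68, a difference of 2.34 (SE 0.44, adjusted p = 0.01). Its call held with the animal as a block. It was lost without PBS animals 1 and 4 (adjusted p = 0.15 and 0.14), without cachexia animals 2, 3 and 4 (0.078, 0.062 and 0.087), and without the libraries that stood apart (0.35). The count of 6 was 2, 3, 3 and 1 without PBS animals 1 to 4, 1, 2 and 1 without cachexia animals 2, 3 and 4, and 0 without the libraries that stood apart.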

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

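No test in this part was chosen after its result was seen.

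Saa1 levels held the most far values. In each group of 4 animals the highest or lowest value was compared with the other 3, for depth, share of rRNA-like reads and the 8 genes followed throughout. In 180 groups 8 values stood far off, and chance alone gives about 1 in 20. Cachectic 8025 animal 3 had low Saa1 in both of its libraries, at a log2 level of 6.71 in hepatocyte nuclei (others 8.50 to 8.76) and 6.73 in whole liver nuclei (others 8.45 to 8.70), still above its PBS animals. A further 4 Saa1 values stood off in whole liver nuclei: 10.03 in cachectic C26 animal 3 (others 9.20 to 9.30), 2.51 in 8025 PBS animal 4 (1.47 to 1.64), -0.24 in MC38 PBS animal 1 (0.26 to 0.31) and 3.16 in MC38 tumour animal 4 (0.74 to 1.04). Nr1d1 stood at 5.95 in whole liver nuclei of MC38 PBS animal 3 (6.96 to 7.13), and rRNA-like reads made up 3.49% of counts in MC38 PBS animal 4 (2.20% to 2.4% in the others).

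Tumour effects differed between cachectic and weight-stable models by the test of the difference itself (edgeR). Between C26 and NC26 it called 251 genes, among them Itih3, with a log2 difference of 2.50 (SE 0.54, adjusted p = 0.011; all 4 cachexia values above all 4 PBS values). Igfbp1 differed by 3.95 (SE 1.05, adjusted p = 0.043), and by 4.65 without C26 PBS 1, 3.17 without C26 cachexia 4 and 3.32 without NC26 PBS 3. Its call was lost without any of the 16 libraries except C26 PBS 1, C26 cachexia 2 and NC26 PBS 2 (adjusted p = 0.052 to 0.13), and with the replicate number as a block (adjusted p = 0.15). Between 8025 and MC38 the test called 957 genes, with log2 differences of 2.48 for Arntl (SE 0.71, adjusted p = 0.028), 3.95 for Lbp (SE 0.74, adjusted p = 0.0012), 3.0 for Itih3 (SE 0.55, adjusted p = 9.1e-04), 4.20 for Igfbp1 (SE 0.99, adjusted p = 0.0088) and 4.91 for Saa1 (SE 1.37, adjusted p = 0.025). Between C26 and 8025 it called 127 genes, and between the fractions of 8025 animals 6.

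Other splits of the same animals into groups of equal size were set beside these counts, without correction for the number of counts. The real split called the most genes for C26 cachexia (2953, against at most 1801 in the other 34 splits, with C26 PBS 1 and cachexia 4 exchanged). The same held for 8025 (3889, at most 319), for NC26 (43, at most 1) and for cachexia against pre-cachexia (1206, at most 785). In each, 1 of 35 splits was as large, the real one, which is the smallest share that 35 splits can give. For C26 pre-cachexia 2 of 35 splits called as many, so chance is not excluded there: the real one called 1025 genes, and 1576 were called with C26 PBS 1 and pre-cachexia 4 exchanged. For MC38 the real count was 0 (edgeR, with 572 genes at an unadjusted p under 0.05, and 6 in DESeq2). All 35 splits reach this whatever they call (up to 50), so they say nothing about chance there. The split with 50 calls exchanged PBS animals 1 and 2 with tumour animals 1 and 4, and the same exchange gave 63 in whole liver nuclei. It groups PBS animals 1 and 2 with tumour animals 2 and 3, whose animal numbers are consecutive. A difference between number series can thus lie behind these calls.

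For the differences, 100 splits were drawn that exchange animals between the groups. Between C26 and NC26, 4 of 100 splits, the real one included, called as many as the real 251 genes (at most 1344). Between 8025 and MC38, 3 of 100 did (957 genes, at most 2271). Between C26 and 8025, 5 of 100 did (127 genes, at most 1242), in splits that exchanged cachexia and PBS animals within each cohort. Such splits do not hold the change shared by both models fixed, so they decide nothing about chance in this difference. The splits at the top between C26 and NC26 and between 8025 and MC38 exchanged only PBS animals, among them C26 PBS 1 or 8025 PBS 1. All cachexia and tumour animals kept their groups there, so the real difference between them stayed in these counts. These splits are therefore no clean measure of chance either.

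In whole liver nuclei the real split called the most genes for C26 cachexia (3039, at most 25 in the others) and pre-cachexia (1753, at most 562). It also did for 8025 (5026, at most 1151) and NC26 (100, at most 1), with 1 of 35 splits as large in each. For MC38 the real count was again 0 (edgeR; 790 at an unadjusted p under 0.05; 14 in DESeq2; up to 63 in other splits), and the 35 splits decide nothing. Between the fractions of PBS animals the real split called the most genes too (7154, at most 3669), with 1 of 100 as large. The same holds for the fraction difference of the 8025 change (6; 1 of 35, at most 0), though leaving out single animals gave 1 to 5 genes: 2, 3, 3 and 1 without PBS animals 1 to 4, and 1, 2 and 1 without cachexia animals 2 to 4. For the C26 change the splits decide nothing, since the real count was 0 (edgeR; 295 at an unadjusted p under 0.05; 1 in DESeq2; at most 2 in the other of the 35 splits). With the animal as a block the test called 62 genes, for which no splits were fitted.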

How the results depend on the processing

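All alternatives were chosen in advance except 3 chosen after the data were seen: the fits without the 5 genes with rRNA-like reads, the fits without the libraries that stood apart, and size factors of DESeq2 for the genes called in both cachexia models (1637 with the same sign). A planned fit without mitochondrial and ribosomal RNA genes was not run, since the table holds none. Named genes gave 228 results, of which 189 were called. Of the called ones 160 were called in every alternative run, and 26 lost the call when 1 replicate was left out. None of the called ones changed sign.

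By another tool, DESeq2 called 143 genes in NC26 hepatocyte nuclei (43 in edgeR), 6 in MC38 (0), 506 between C26 and NC26 (251) and 355 between C26 and 8025 (127). In whole liver nuclei it called 199 in NC26 (100) and 14 in MC38 (0), and between fractions 1 in C26 (0) and 14 in 8025 (6). It moved 5 of 228 named results past the threshold and none below, and made more false calls than edgeR in simulations. Size factors of DESeq2 in edgeR gave 3 genes between fractions in 8025 (6) and took the call from 2 named results. Leaving out the low-count filter or the 5 genes with rRNA-like reads changed no named call.

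Fitting only the cohorts compared gave 404 genes in C26 pre-cachexia (1025), 776 between cachexia and pre-cachexia (1206), 54 between C26 and 8025 (127), 2981 in 8025 whole liver nuclei (5026) and 3 between fractions in 8025 (6). It took the call from 14 of 220 named results and gave it to 1. Without the libraries that stood apart there were 1723 genes in C26 pre-cachexia, 489 between C26 and NC26 and 1111 in whole liver nuclei before cachexia (1753). Between fractions in 8025 there were 0, with only PBS animals 2 and 4 left in their group (edgeR, and 14 in DESeq2 with all libraries). Of 228 named results 10 lost the call.

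Replicate numbers were not taken to pair tumour with PBS animals. Animal numbers in the labels form series that hold both PBS and tumour animals, in MC38 and NC26 partly under other replicate numbers. These series were not fitted as a block, so their effect on the counts of called genes is not known. Of 48 same-number pairs 10 had a correlation of deviations over 0.1 (range -0.27 to 0.40), and in 0 of 12 pairs of groups did all 4 numbers pass it (nearest were PBS and pre-cachexia hepatocyte nuclei of C26, with 0.22, 0.15, 0.07 and 0.40); nor did every library correlate best with its own number. The replicate number as a block gave 1 gene in MC38 hepatocyte nuclei (0 without it), 78 between C26 and 8025 (127) and 49 in NC26 whole liver nuclei (100). Of 219 named results 10 lost the call, and Lbp in MC38, not called, turned from -0.35 to 0.05. Both libraries of an animal do pair, and the replicate block of the animal gave 62 genes between fractions in C26 (0) and 190 in 8025 (6), and 22 lists between fractions in PBS animals (12) and 11 for the 8025 change (0 by camera without the block).

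With an estimated correlation in place of the preset one, camera called fewer lists in hepatocyte nuclei: 1 in C26 cachexia (16 at the preset), 1 in pre-cachexia (12), 6 in 8025 (17), 0 in NC26 (11), 0 in MC38 (10), 1 between cachexia and pre-cachexia (11), and 0 between C26 and NC26 (12), 8025 and MC38 (20), and C26 and 8025 (17). In whole liver nuclei it called 3 in C26 (18), 0 in pre-cachexia (16), 6 in 8025 (20), 0 in NC26 (14) and 0 in MC38 (12). Between fractions it called 6 in PBS animals (12) and 0 for the C26 change (9). The fry check called 18 lists in C26 cachexia, 9 in pre-cachexia, 22 in 8025, 2 in NC26 and 0 in MC38 hepatocyte nuclei. It called 13 between cachexia and pre-cachexia, 4 between C26 and NC26, 16 between 8025 and MC38, and 1 between C26 and 8025. In whole liver nuclei fry called 20, 12, 27, 7 and 2, in the same order of groups. Between fractions it called 25 in PBS animals and 0 for either change.

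Leaving out each replicate in turn gave these ranges of called genes in hepatocyte nuclei: 2129 to 3045 in C26 cachexia, 333 to 1626 in pre-cachexia, 3046 to 3802 in 8025, 4 to 94 in NC26, 0 to 5 in MC38 and 568 to 1412 between cachexia and pre-cachexia. They were 137 to 479 between C26 and NC26, 623 to 1080 between 8025 and MC38 and 51 to 220 between C26 and 8025. In whole liver nuclei they were 2413 to 2704, 932 to 2458, 4176 to 5202, 24 to 136 and 0 to 10, in the same order of groups, and between fractions 0 to 0 in C26 and 1 to 5 in 8025. Genes called in both cachexia models with the same sign were 1306 to 1673 (1669 with all animals). Of 2024 named values 135 lost the call, 3 gained it and 15 turned sign, none of them called. Those were Nr1d1 (-0.17 to 0.59 over all libraries left out), Nr1d2 (-0.14 to 0.18) and Arntl (-0.88 to 0.63) in pre-cachexia, Arntl (-0.41 to 0.42) and Igf1 (-0.35 to 0.48) in NC26, and Nr1d2 (-0.13 to 0.08), Lbp (-0.64 to 0.46) and Igfbp1 (-0.31 to 0.56) in MC38.

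The correlation of C26 pre-cachexia and cachexia changes was 0.59 with shared controls, and 0.38, 0.42, 0.32, 0.41, 0.44 and 0.43 with the PBS animals divided in each of 6 orders.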

Other observations

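The tests of marker ratios, heat shock levels, sex-biased lists and cell cycle ratios below were chosen only after the result was seen.

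Further genes changed in hepatocyte nuclei beside the groups described above. Mt1 (chromosome 8, 94179089 to 94180327), the second metallothionein, rose to 259 ± 49.1 CPM from 5.78 ± 3.18 CPM in C26 (SD, n = 4 each; 44.8-fold; adjusted p = 3.7e-06) and 84.1-fold in 8025 cachexia. Iron and metal handling was called higher in C26 (10 of 25 rose and 3 fell, 10 and 4 adjusted over the list alone; adjusted p = 0.042, and adjusted p = 0.36 with an estimated correlation) and in 8025 (9 and 4; 10 and 5 adjusted over the list alone; adjusted p = 0.027, and adjusted p = 0.19 with an estimated correlation). Ahsg (chromosome 16, 22892015 to 22899451), which encodes fetuin A, rose 2.60-fold in C26, and the complement gene C4b (chromosome 17, 34728381 to 34743897) 3.62-fold in 8025. Acaa1b (chromosome 9, 119148043 to 119157093), a peroxisomal thiolase, fell 26.7-fold in C26 (log2 fold change -4.74, and -5.82 without cachexia animal 1). Csad (chromosome 15, 102176998 to 102189043), a taurine synthesis enzyme, fell 6.88-fold already before cachexia.

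Lists of genes along the axis of the liver lobule were called between the models at the preset correlation alone. Pericentral genes, expressed near the central vein, had a lower change in C26 than in 8025 (1 of 24 called, 3 adjusted over the list alone; median log2 difference -0.74; adjusted p = 1.2e-04), and periportal genes a higher change (1 of 23, 1 adjusted over the list alone; 0.53; adjusted p = 0.0029). Each had adjusted p = 0.25 with an estimated correlation. Genes of the growth hormone and IGF axis had a higher change in C26 as well (2 of 22 higher; 3 higher and 2 lower adjusted over the list alone; adjusted p = 0.0039, and adjusted p = 0.25 with an estimated correlation). Cholesterol synthesis had a higher change in 8025 than in MC38 (3 of 25, 3 adjusted over the list alone; median 0.68; adjusted p = 0.0037, and adjusted p = 0.54 with an estimated correlation). Hepatocyte transcription factors were called lower in 8025 (7 of 28 fell and 1 rose, the same counts adjusted over the list alone; adjusted p = 0.021, and adjusted p = 0.25 with an estimated correlation).

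Macrophage markers were higher in hepatocyte nuclei of cachectic 8025 animals, by 1.42 on the mean log2 level (SE 0.12, exact permutation p = 0.029, the smallest that 4 against 4 animals can give), while the rise of 0.56 in C26 (SE 0.21, exact permutation p = 0.086) missed the threshold. In 8025 a larger share of other nuclei in the bead fraction is argued against, since the ratio of hepatocyte to whole liver nuclei changed by 0.19 (SE 0.14) for endothelial markers. What stays open is the same small share from livers that hold more macrophage RNA: the markers rose by 1.47 (SE 0.16) in whole liver nuclei, and their ratio changed by -0.05 (SE 0.12). The 8025 rise in hepatocyte nuclei may therefore come from macrophage nuclei that pass the purification, of which Mrc1 kept 12.9% in PBS animals. In C26 the tests left both open, with ratio changes of 0.21 (SE 0.24) for endothelial and 0.19 (SE 0.20) for macrophage markers, and transcription of such genes in hepatocytes was not tested.

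Some heat shock genes were lower in C26 animals than in their PBS animals, such as Hspa1b (chromosome 17, 34956429 to 34959238), an inducible HSP70, at 0.0898 ± 0.0722 CPM in cachexia against 7.99 ± 7.92 CPM (log2 fold change -6.39, and -5.53 without PBS animal 3). Their list of immediate early and heat shock genes was not called (adjusted p = 0.11 in cachexia and 0.5 before it), and the mean log2 level of its 8 heat shock members, grouped only after their fall was seen, fell by 2.30 (SE 0.39, exact permutation p = 0.029) in cachexia and by 1.62 (SE 0.47, exact permutation p = 0.057) before it, so that these p-values are no independent evidence of a fall. PBS animals of the C26 cohort held 1.26 more (SE 0.43, exact permutation p = 0.057) than PBS animals of the same strain in the NC26 cohort, so that part of the fall may come from a high level in these PBS livers, for example from handling. Cachectic C26 animals still lay below NC26 PBS animals by a difference of -1.05 (SE 0.30, exact permutation p = 0.029), so a fall with cachexia or with the tumour itself stays open: 8025 cachexia gave -0.45 (SE 0.21, exact permutation p = 0.057), NC26 tumours -0.59 (SE 0.36, p = 0.17) and MC38 tumours -0.05 (SE 0.17, p = 0.77) against their own PBS animals. Cohort and library series coincide and cannot be told apart, and edgeR called 0 genes between these PBS groups (1208 of 13274 at an unadjusted p under 0.05; DESeq2 was not run).

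Several genes that fell in cachexia are known as male-biased in mouse liver, such as Mup21, Slco1a1 and Hsd3b5 in both models and Cyp4a12a in 8025 (not called in C26, adjusted p = 0.088), and some that rose as female-biased, such as Cyp17a1 in both and Cux2 in C26 (not called in 8025, adjusted p = 0.12). All 36 hepatocyte libraries carried RNA of the Y chromosome (Ddx3y at 76.1 to 146 CPM). A male-biased and a female-biased list were tested by camera with adjustment over these 2 lists alone, not over all lists of a comparison. Their adjusted p is therefore less strict than that of the other lists. The male-biased list kept Mup1 and Mup12, which share reads with the named Mup genes. With the genes named by the rule left out, 12 of 25 male-biased genes fell and 1 rose in C26 (adjusted p = 7.4e-08, and adjusted p = 0.0076 with an estimated correlation) and 10 fell in 8025 (adjusted p = 8.7e-06, and adjusted p = 0.034 with an estimated correlation). Of 17 female-biased genes 10 rose and 1 fell in C26 (adjusted p = 0.0011, and adjusted p = 0.087 with an estimated correlation) and 7 rose and 2 fell in 8025 (adjusted p = 0.041, and adjusted p = 0.27 with an estimated correlation). A candidate explanation is a shift of the sex-biased programme towards the female side, with medians of both lists 3.64 apart in C26 and 2.58 in 8025; growth hormone and sex steroids, which govern this programme, were not measured here.

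Cell cycle genes were higher before cachexia than in it, and other cycling cells that pass the beads stay open as a source: the log2 ratio of hepatocyte to whole liver nuclei lay 0.37 (SE 0.17) above the midpoint between macrophage and hepatocyte markers over the whole list, but only 0.04 (SE 0.30) above it over the 12 members called. Pre-cachexia animals 1 and 3 had 317 and 339 CPM of Saa1 in hepatocyte nuclei, and animals 2 and 4 had 13.6 and 17.6 CPM. Library C26 PBS 1 held 38858 CPM of Cmss1, a gene with rRNA-like reads, and without it the pre-cachexia count was 1626 genes in place of 1025. Of the 42 genes that rose under NC26 tumours 40 also rose in C26 cachexia, although NC26 is a weight-stable tumour per the labels.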
